A study of Mus musculus with 4 samples.

How the data were processed

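RNA from sorted marrow cells was extracted with Trizol, amplified with a SMARTer low-input kit and sequenced as paired-end reads on an Illumina HiSeq, per the labels' protocols. Reads were aligned with Bowtie 0.12.2 to the mouse build mm9, per the submitters' processing notes. The program that counted reads and its handling of strand and of reads with several alignments are not given in the sources used here, so genes that overlap or have near-identical copies can share reads. The deposited values are whole-number counts per RefSeq transcript, with no normalisation, in 1 table per library.

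Each table held 33018 transcripts of 24016 gene symbols, in the same order. Sums over all transcripts were 63962609 and 55295762 in WT and 52531850 and 72655188 in NHD13, and 1690 of the 4911 symbols with more than 1 transcript had transcripts with identical counts, so reads were counted in more than 1 transcript. Each gene was therefore represented by the transcript with the highest total over all 4 libraries. Among genes tested, 52 had counts identical to those of another symbol. The ribosomal RNA precursor Rn45s took 2.73 to 3.40 percent of counts per library. Gene names were used as the files give them and no coordinates were used.

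Counts were tested with edgeR 4.0.16 (R 4.3.3) after its default filter on low counts and TMM scaling, by the robust quasi-likelihood test of NHD13 against WT on all 4 libraries, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. CPM are counts scaled by the TMM-normalised library totals, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. The average biological coefficient of variation was 26.9 percent. Where a group had 0 counts in all, a bound was set with 3 counts over the group, and where it had 1 to 3 an exact binomial 95% interval of the ratio was used.

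The 35 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Named genes were chosen by a rule fixed at the same time: the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1, no overlap between groups and no predicted or clone-based name; up to 4 members of each list with the smallest adjusted p, or 2 where none was called; and the partner genes of the transgene, gate genes, Hoxa genes, Meis1 and Pbx3. A few genes that the rule takes are not reported here. Other genes named beside a list, such as Procr, Mecom, S100a8, Ngp, Cd3g, Gzmb, Sparc, Ms4a2, H2-Ob, Cdkn1a, Prtn3, Cd74 and Hspa1a, were chosen after their values were seen.

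The test was run on simulated counts with the real means, library sizes and dispersions and 200 genes changed per run, over 5 runs of 14592 to 14616 genes for the comparison of NHD13 with WT. With each gene's own dispersion it recovered 37.6 percent of genes changed 2-fold and 70.0 percent of those changed 4-fold, and 16.1 percent of its calls (11.1 to 21.2 percent per run) were unchanged genes. With dispersions taken from the trend that share was 3.47 percent. An adjusted p of 0.05 can thus carry more false calls than 5 percent at 2 libraries per group. With each gene's own dispersion the simulated runs gave 111 to 146 calls, against 636 in the real data. The share of false calls and the share of changed genes recovered both depend on how many genes change, so the simulated shares need not hold for the real data.

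Alternatives were other scalings (DESeq2 size factors, library totals), no filter or a stricter one, DESeq2 1.42.0, limma-voom, a non-robust fit, other thresholds, the replicate number as a block, and leaving out each library in turn. Summed transcripts, a test of every transcript, leaving out Rn45s and crossed replicate numbers were added after seeing the data.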

Results

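RNA was sequenced from hematopoietic stem cells sorted from mouse bone marrow at 4 months of age. The sort kept lineage-negative cells positive for Sca-1, c-Kit and CD150 and negative for CD34 and Flt3. The wild-type (WT) group had 2 libraries and the NHD13 group had 2. NHD13 mice carry a transgene for the fusion of NUP98 with HOXD13, a model of myelodysplastic syndrome. With 1 transcript per gene, the libraries held 42664018 and 37070939 counts in WT and 35025974 and 48423689 in NHD13. Within each group the libraries differed by more than counting noise, with a mean chi-square per gene of 36.6 in WT and 62.9 in NHD13 on 1 degree of freedom. The labels do not say whether the libraries of a group came from separate animals or pools. Each library held Xist, made by female cells, at 104 to 665 CPM and the Y-linked Ddx3y at 91.9 to 169 CPM, which points to material of both sexes, and so of more than 1 animal, in each unless RNA or reads crossed between samples. An n of 2 then counts libraries, not animals, and SDs and p-values measure only the spread between these samples.

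The comparison asked how gene expression differs between stem cells sorted from NHD13 and WT marrow. NHD13 cells had a high level of Cd48, which encodes a surface protein used to tell progenitors from stem cells, at 245 CPM ± 30.8 (SD, n = 2) against 4.95 ± 0.166 in WT. They also had higher Mpo, the myeloperoxidase of granulocyte precursors, at 648 ± 86.5 against 44.1 ± 6.90 CPM, and expressed Hoxc genes that were near 0 in WT. Clec1a, a lectin-like receptor gene, was lower at 3.50 ± 0.0368 against 142 ± 10.3 CPM, and Ndn, a gene linked to stem cell quiescence, was lower at 2.52 ± 0.104 against 86.8 ± 0.769 CPM. The MHC class II genes H2-Aa and H2-Eb1 were also lower. Of 14853 genes tested by edgeR's quasi-likelihood test, 636 passed an adjusted p of 0.05, 307 higher and 329 lower in NHD13.

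The number of calls varied widely when a library was left out. Each such fit takes its spread from the group that still has a pair, so a lost call need not trace to the library left out. Without WT library 1 or WT library 2, edgeR called 0 genes, with 2332 and 2605 genes at an unadjusted p under 0.05, while DESeq2 called 1001 and 1131 and limma-voom 0 in both; without NHD13 library 1 edgeR called 270 genes and without NHD13 library 2 it called 990. In each of these fits, all 636 called genes kept their direction, which was close to given, as the fits reused libraries that had selected these genes. Scaling also moved genes near the threshold: with library totals only, Hoxb5, Cd79a, Fcer1a, Rbl2, Plk2, Nfkb1, Jarid2 and Snhg18, all reported below as called, missed it with an adjusted p of up to 0.0616.

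Transcripts of the transgene's partner genes were examined first. The mouse gene Hoxd13 had 14 and 3 counts in WT and 65 and 78 in NHD13, a log2 fold change of 3.07 ± 0.76 (SE) with an adjusted p of 0.0893 (0.0156 by DESeq2). Nup98 was at 159 ± 1.26 CPM in WT and 161 ± 1.10 in NHD13 (log2 fold change 0.02 ± 0.08). The transgene is a human sequence, and how its reads align to the mouse genes was not measured. Among the genes of the sort gate, Kit (-0.18 ± 0.11) and Slamf1, which encodes CD150 (0.04 ± 0.14), had log2 fold changes within 2 standard errors of 0, and that of Slamf1 was below 0 without WT library 1 or NHD13 library 1. Ly6a, which encodes Sca-1, had -1.18 ± 0.30 (adjusted p 0.0921, or 0.00039 by DESeq2). Cd34 had -1.82 ± 0.42 (adjusted p 0.0796) and was called by DESeq2 (0.0224) and without NHD13 library 1 (0.0240) or NHD13 library 2 (0.0348). Flt3 stood apart in NHD13 library 1, at 58.96 CPM against 4.33 in NHD13 library 2 and 10.4 and 15.4 in WT, and was called higher without NHD13 library 2 (adjusted p 0.0399).

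Homeobox genes of the Hoxc and Hoxd clusters, which pattern the body axis, rose in NHD13 cells. Of 17 members of the list 9 passed the filter on low counts. Among these 9 tested members 6 were called, all higher, and 8 were called higher adjusted over the list alone. Members near absent in WT, such as Hoxc8 with 6 and 1 counts there, passed the filter only through the NHD13 libraries. For them a rise was a condition of being tested, so the direction, median and test of this list were in part given. Hoxc8 was at 37.6 ± 3.78 CPM against 0.0827 ± 0.0782 in WT (log2 fold change 8.71 ± 0.45). Hoxc4 (6.98 ± 0.66), Hoxc5 (6.92 ± 0.50) and Hoxc6 (4.75 ± 0.27) rose in both NHD13 libraries, as did Hoxc9. Hoxd3 had 1 count in the WT group and 79 in the NHD13 group, a ratio of 75.9 with a 95% counting interval of 13.2 to 3033. The list median was 5.93, or 4.75 with the 2 members of very few counts at the lower ends of their counting intervals. The list was called higher by camera (adjusted p 2.22e-25; adjusted p = 0.464 with an estimated correlation).

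**Figure D1:**
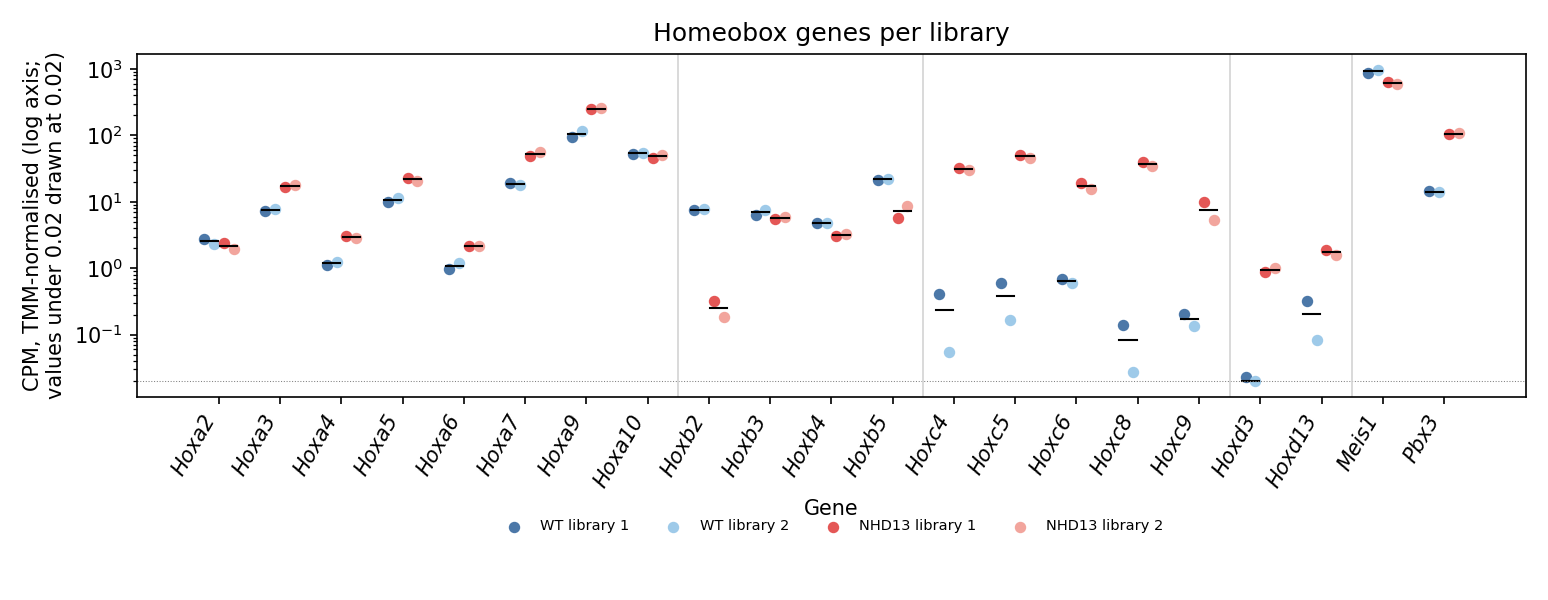
Expression of Hox genes and of their cofactors Meis1 and Pbx3 in each library, as TMM-normalised CPM on a log axis. Points are libraries and bars are group means of 2; Hoxc8 lies at 40.3 and 34.9 CPM in NHD13 and below 0.2 CPM in WT.

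In the Hoxa cluster, whose genes are active in stem cells and many leukemias, 4 of 10 tested members were called, all higher. Hoxa9 was at 253 ± 1.47 CPM against 104 ± 14.0 (log2 fold change 1.28 ± 0.12), and Hoxa7 (1.49 ± 0.14), Hoxa3 (1.22 ± 0.17) and Hoxa5 (1.04 ± 0.17) were also called. Among members that were not called, Hoxa4 had a log2 fold change of 1.30 ± 0.37, Hoxa6 1.0 ± 0.41, Hoxa2 -0.24 ± 0.36 and Hoxa10 -0.14 ± 0.11, and Hoxa11 had 1 count in WT and 93 in NHD13 and was called without a filter (adjusted p 0.0419) and by DESeq2 (0.00976). The list was called higher (camera adjusted p 7.52e-05; adjusted p = 0.464 with an estimated correlation), with 6 members higher adjusted over the list alone. No Hoxa gene was called by edgeR without WT library 1 or WT library 2, with 5 at an unadjusted p under 0.05 in each fit and 3 and 4 called by DESeq2 and 0 by limma-voom; without NHD13 library 1 there was 1 call and without NHD13 library 2 there were 2. In the Hoxb cluster Hoxb2 fell by 4.93 ± 0.43 and Hoxb5 fell by 1.59 ± 0.24 on the log2 scale, 2 of 8 tested members (3 lower and 1 higher adjusted over the list alone), and the list was not called (camera adjusted p 0.133), though it was called lower under the filter of 1 CPM in both libraries of a group (adjusted p 0.0138). Among the TALE homeobox partners of Hox proteins, Pbx3 (2.90 ± 0.11) and Pbx4 (1.35 ± 0.21) rose, while Meis1 had -0.59 ± 0.10 (adjusted p 0.0511) and was called with library totals only (0.0393), without a filter (0.0250), under the stricter filter (0.0325) and by DESeq2. That list was not called (adjusted p 0.233; 2 higher and 3 lower adjusted over the list alone), and its median of -0.07 and mean of -0.40 lay opposite to the direction of the test.

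Genes of stem cell identity were lower. Of 40 tested members 7 fell and 0 rose by edgeR over all genes; adjusted over the list alone, 18 were lower and 4 higher. On the log2 scale Ndn (-5.10 ± 0.13), Mllt3 (-1.89 ± 0.12), Clca1 (-1.49 ± 0.14) and Ctnnal1 (-1.04 ± 0.11) fell. Hlf, a transcription factor of stem cells, and Angpt1, the ligand of the receptor Tie2, also fell. Procr (-0.01 ± 0.20) and Mecom (-0.09 ± 0.21), further genes of the list, were not called. As a list they were lower by camera (adjusted p 5.12e-10, and adjusted p = 0.464 with an estimated correlation). The fall was uneven between libraries. Relative to the mean of all libraries, the list median on the log2 scale was -0.582 in NHD13 library 1 and -0.088 in NHD13 library 2. In WT it was 0.265 and 0.388.

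Granulocyte and monocyte genes were higher, 6 of 33 tested members called and none lower, with 10 higher adjusted over the list alone. Mpo (3.88 ± 0.17), Plac8 (3.93 ± 0.24), Ms4a3 (3.24 ± 0.27) and Nkg7 (2.67 ± 0.32), together with the granule protease genes Ctsg and Elane, rose in both NHD13 libraries. The protease gene Prtn3 had a log2 fold change of -0.46 ± 0.17. Genes of later neutrophil granules stood high in NHD13 library 1 alone: S100a8 was at 640 CPM there, 80.1 in NHD13 library 2 and 78.7 and 69.9 in WT, and Ngp was at 915 against 132, 94.3 and 70.1 CPM. None of 13 tested late granulocyte genes was called by edgeR on all 4 libraries, with 4 at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0. Without NHD13 library 2 edgeR called 12 of them. Camera called the granulocyte and monocyte list higher (adjusted p 2.13e-13; adjusted p = 0.558 with an estimated correlation). Its median was 2.34, and 0.39 without NHD13 library 1, where it was still called (adjusted p 0.00013).

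**Figure D2:**
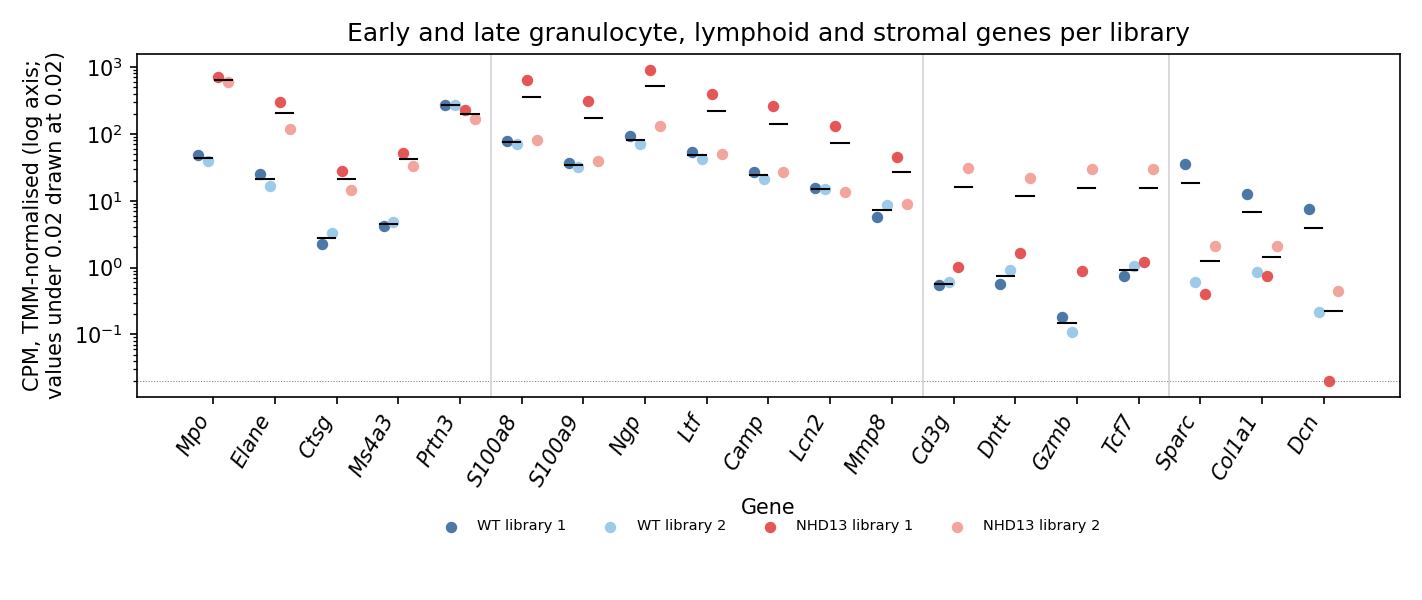
Early granulocyte, late granulocyte, lymphoid and stromal genes, left to right, in each library, as TMM-normalised CPM on a log axis. Points are libraries and bars are group means of 2; Mpo is high in both NHD13 libraries, S100a8 and Ngp in NHD13 library 1, Cd3g and Gzmb in NHD13 library 2 and Sparc in WT library 1.

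Genes of the lymphoid progenitor and lymphocyte list were higher in number but uneven between libraries. Cd53 (2.70 ± 0.21), Cd37 (1.77 ± 0.24) and Cd79a (1.65 ± 0.26) rose, 3 of 27 tested members and also 3 adjusted over the list alone. The list was called higher (camera adjusted p 0.00128; adjusted p = 0.558 with an estimated correlation), but not without NHD13 library 2 (adjusted p 0.0666). Its median of 1.29 was 0.19 without that library, 0.32 without NHD13 library 1 and 0.53 without WT library 2. Cd3g, of the T cell receptor complex, was at 30.8 CPM in NHD13 library 2 and 1.02 in NHD13 library 1, and Gzmb was at 30.3 and 0.873 CPM. Neither was called by edgeR (adjusted p 0.156 for Cd3g and 0.118 for Gzmb). Among 17 stroma and endothelium genes none was called by edgeR with its default filter on all 4 libraries (5 at an unadjusted p under 0.05; 4 called by DESeq2 and 0 by limma-voom), with 0 adjusted over the list alone, and the list was not called (camera adjusted p 0.195), though it was called lower without WT library 2 (adjusted p 0.000782) or NHD13 library 2 (adjusted p 0.0334). Pdgfrb (1.80 ± 0.37) and Flt4 (-2.48 ± 0.60) had the smallest p in it. Under the filter of 1 CPM in both libraries of a group edgeR called 1 member, Flt4 (adjusted p 0.0468), and without NHD13 library 2 it called 3. Sparc was at 35.6 CPM in WT library 1 against 0.602 in WT library 2. In the macrophage list (adjusted p 0.233; 3 higher and 0 lower adjusted over the list alone) Cd68 rose by 1.67 ± 0.14. In the mast cell and basophil list (camera adjusted p 0.625, with 3 higher and 2 lower adjusted over the list alone) Il4 fell by 4.79 ± 0.39. The Il4 counts were those of a transcript annotated as non-coding. Fcer1a had 102 counts in WT and 1 in NHD13, while Ms4a2 was at 111 CPM in NHD13 library 1 and 4.45 in NHD13 library 2. The erythroid list was not called (adjusted p 0.156; 5 higher and 1 lower adjusted over the list alone), though it was called higher without WT library 1 (adjusted p 0.00489).

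Megakaryocyte and platelet genes were lower on balance, 5 of 26 tested members lower and 1 higher, or 10 lower and 3 higher adjusted over the list alone. Mmrn1, a platelet granule protein gene, fell by 3.55 ± 0.40, from 1358 ± 186 to 116 ± 59.3 CPM, and was not called without a filter on low counts (adjusted p 0.0847). Sdpr (-2.38 ± 0.25) and the transcription factor gene Fli1 (-0.80 ± 0.10) fell, while the thrombin receptor gene F2r rose by 1.21 ± 0.12. The list was called lower by camera (adjusted p 0.00896; adjusted p = 0.464 with an estimated correlation) and by fry (adjusted p 0.0316), but not by camera without NHD13 library 2 (adjusted p 0.0856).

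Among 16 MHC class II presentation genes 5 were called lower and none higher over all genes, with 7 lower and 3 higher adjusted over the list alone; 7 log2 fold changes were above 0. The log2 fold changes were -3.61 ± 0.11 for H2-Aa, -3.16 ± 0.14 for H2-Eb1, -1.97 ± 0.16 for H2-Ab1 and -2.46 ± 0.35 for their transactivator gene Ciita. Cd74, the invariant chain, had -0.70 ± 0.26 and was not called, and H2-Ob was at 178 and 49.98 CPM in NHD13 against 8.12 and 11.5 in WT (adjusted p 0.0627). Camera called this list lower (adjusted p 5.91e-07; adjusted p = 0.464 with an estimated correlation), but not without NHD13 library 2 (adjusted p 0.190).

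Cell cycle genes were higher. Of 40 genes of G2 and mitosis 9 were called, all higher, and all 40 had a log2 fold change above 0; adjusted over the list alone, 32 were higher. The spindle motor gene Kif11 rose by 1.53 ± 0.12, Ndc80 by 1.17 ± 0.13, Hmmr by 1.11 ± 0.13 and Cenpe by 1.22 ± 0.16. Of 38 S phase genes Ccne2 (1.16 ± 0.16) was the 1 called, with 27 higher and 1 lower adjusted over the list alone. Relative to the mean of all libraries, the S phase median on the log2 scale was 0.545 in NHD13 library 1 and 0.096 in NHD13 library 2. In WT it was -0.290 and -0.376. Both lists were called higher (camera adjusted p 6.95e-22 and 1.97e-10; adjusted p = 0.558 for each with an estimated correlation). Cdk6, a kinase of the G1 phase, rose by 2.41 ± 0.13, while Ccnd3 (-0.83 ± 0.10) and Rbl2 (-0.67 ± 0.11) fell; their list of cell cycle inhibitors and quiescence was not called (adjusted p 0.896; 1 higher and 2 lower adjusted over the list alone). With the default filter and no block, edgeR called no DNA repair gene of 53 on all 4 libraries, over all genes or adjusted over the list alone, though 49 had a log2 fold change above 0 and 18 an unadjusted p under 0.05; DESeq2 called 12 and limma-voom 0. Without a filter it called 3, with Exo1 and Prkdc among them (adjusted p 0.0403 and 0.0439), with the crossed pairing as a block 2 and without NHD13 library 2 also 2. Exo1 had 0.77 ± 0.16 and Prkdc 1.01 ± 0.23, and the list was called higher (camera adjusted p 0.000518; adjusted p = 0.569 with an estimated correlation).

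Adhesion and homing receptors changed in both directions, 5 higher and 2 lower of 27, or 7 higher and 7 lower adjusted over the list alone. Besides Cd48 (5.63 ± 0.15), the integrin genes Itgal (3.49 ± 0.31), Itgb7 (1.58 ± 0.14) and Itga4 (1.57 ± 0.10) rose. The list was called higher by camera (adjusted p 0.000751; adjusted p = 0.464 with an estimated correlation) and fry (adjusted p 0.0166). Camera did not call it without WT library 1 (adjusted p 0.149), NHD13 library 1 (0.297) or NHD13 library 2 (0.349).

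The immediate early and TGF-beta lists were called lower (camera adjusted p 0.00667 for each; adjusted p = 0.464 and 0.505 with an estimated correlation), while the Notch and Wnt lists were not called. In the immediate early and stress list 6 of 35 fell and 1 rose, with 10 lower and 3 higher adjusted over the list alone: Nr4a1 (-1.42 ± 0.17), Egr1 (-0.81 ± 0.10), Ier3 (-1.10 ± 0.12) and Cyr61 (-2.85 ± 0.32) fell, while the heat shock gene Hspa1a rose by 1.52 ± 0.25. Of the TGF-beta and BMP pathway, Id1 (-1.40 ± 0.18) and Id2 (-1.19 ± 0.14) fell, 2 of 30 members, with 5 lower and 0 higher adjusted over the list alone. Camera did not call the immediate early list without WT library 2 (adjusted p 0.181). In the Notch list (adjusted p 0.136; 1 lower adjusted over the list alone) Hes1 fell by 2.25 ± 0.22, and in the Wnt list (adjusted p 0.206; 2 lower adjusted over the list alone) Sfrp1 fell by 5.26 ± 0.54. Of p53 targets 3 of 30 fell, namely Fas (-1.60 ± 0.20), Gdf15 (-2.82 ± 0.36) and Plk2 (-0.89 ± 0.15), also 3 adjusted over the list alone. Camera called the list lower (adjusted p 0.00971; adjusted p = 0.569 with an estimated correlation), but not without WT library 1 (adjusted p 0.395). The p53 target gene Cdkn1a was at 135 CPM in WT library 1 and 47.9 in WT library 2.

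Oncofetal, ribosomal and metabolic lists were tested next. Lin28b (5.05 ± 0.62; adjusted p 0.103 without a filter on low counts), H19 (4.04 ± 0.23) and Igf2 (3.25 ± 0.39), oncofetal genes, rose, and Hmga2 fell by 1.88 ± 0.23. With 4 of 16 members higher and 1 lower, or 6 higher and 4 lower adjusted over the list alone, the list was called higher (camera adjusted p 0.0238; adjusted p = 0.558 with an estimated correlation), but not without NHD13 library 1 (adjusted p 0.0563) or NHD13 library 2 (adjusted p 0.241). Of 82 ribosomal protein genes 81 had a log2 fold change below 0, with a median of -0.23, and with TMM scaling, the default filter and no block none was called by edgeR on all 4 libraries, over all genes or adjusted over the list alone, against 45 at an unadjusted p under 0.05, 22 called by DESeq2 and 2 by limma-voom. Rplp1 had -0.50 ± 0.09 and Rpl14 -0.50 ± 0.09. EdgeR called 3 members with library totals only, 2 without a filter and 6 under the stricter filter, Rplp1 and Rpl14 in each; it also called 3 with the crossed pairing as a block and 1 each without NHD13 library 1 or NHD13 library 2. That list was called lower (camera adjusted p 5.85e-07; adjusted p = 0.569 with an estimated correlation). The glucose transporter gene Slc2a3 fell by 1.23 ± 0.09, 1 of 34 members by either adjustment, over all genes or adjusted over the list alone, and the glycolysis and hypoxia list was called lower (camera adjusted p 0.0261; adjusted p = 0.558 with an estimated correlation), but not without WT library 1 (adjusted p 0.184) or NHD13 library 2 (adjusted p 0.174). Oxidative phosphorylation was not called (adjusted p 0.538) except without NHD13 library 2 (adjusted p 0.0269), where edgeR called 1 member. On all 4 libraries edgeR called 0 of 74, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05; 1 called by DESeq2 and 0 by limma-voom), with Cox4i1 at -0.30 ± 0.08 and Atp5b at 0.23 ± 0.09. In the antioxidant list (adjusted p 0.945; 3 higher and 5 lower adjusted over the list alone) Gpx7 (-2.19 ± 0.21) and Nfe2l2 (-0.71 ± 0.10) fell, and Prdx4 (1.05 ± 0.13) and Ncf4 (2.66 ± 0.40; adjusted p 0.0543 without a filter and 0.0708 by limma-voom) rose.

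Regulators linked to leukemia and immune sensing changed in both directions. Ezh2 (0.80 ± 0.13) and Jarid2 (0.79 ± 0.12), of Polycomb complex 2, rose (Ezh2 had an adjusted p of 0.0503 by limma-voom), with 6 of 34 higher adjusted over the list alone, and the Polycomb and DNA methylation list was called higher by camera (adjusted p 0.0261; adjusted p = 0.464 with an estimated correlation) and fry (adjusted p 0.0166). Camera did not call it without WT library 1 (adjusted p 0.0543) or WT library 2 (0.0528). Ezh2 was the 1 called member of 39 genes mutated in myelodysplastic syndrome, a list called higher (camera adjusted p 0.00896; adjusted p = 0.558 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. Trib2 rose by 1.59 ± 0.16 and, with Cdk6, Id2 and Hlf, was called in the list of leukemia self-renewal regulators, which was not called (adjusted p 0.325; 5 higher and 6 lower adjusted over the list alone). Of interferon response genes Oas2 (2.11 ± 0.28), Oas3 (0.95 ± 0.12) and Psmb8 (0.56 ± 0.09) rose, 3 of 48, or 6 adjusted over the list alone. Camera called the list higher (adjusted p 0.0257; adjusted p = 0.744 with an estimated correlation), but not without WT library 1 (adjusted p 0.779) or NHD13 library 2 (adjusted p 0.173). Among innate sensors (adjusted p 0.557; 7 higher and 5 lower adjusted over the list alone) Tifab (5.04 ± 0.52), Il1b (4.29 ± 0.51) and Casp1 (0.88 ± 0.12) rose and Il18 fell by 1.90 ± 0.17. Among NF-kB targets (adjusted p 0.945; 3 higher and 2 lower adjusted over the list alone) Nfkb1 rose by 0.78 ± 0.11, and the list's median of 0.13 and mean of 0.19 lay opposite to the direction of the test. Among apoptosis regulators (adjusted p 0.765) Fas was the 1 called gene, with 2 higher and 1 lower adjusted over the list alone.

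**Figure D3:**
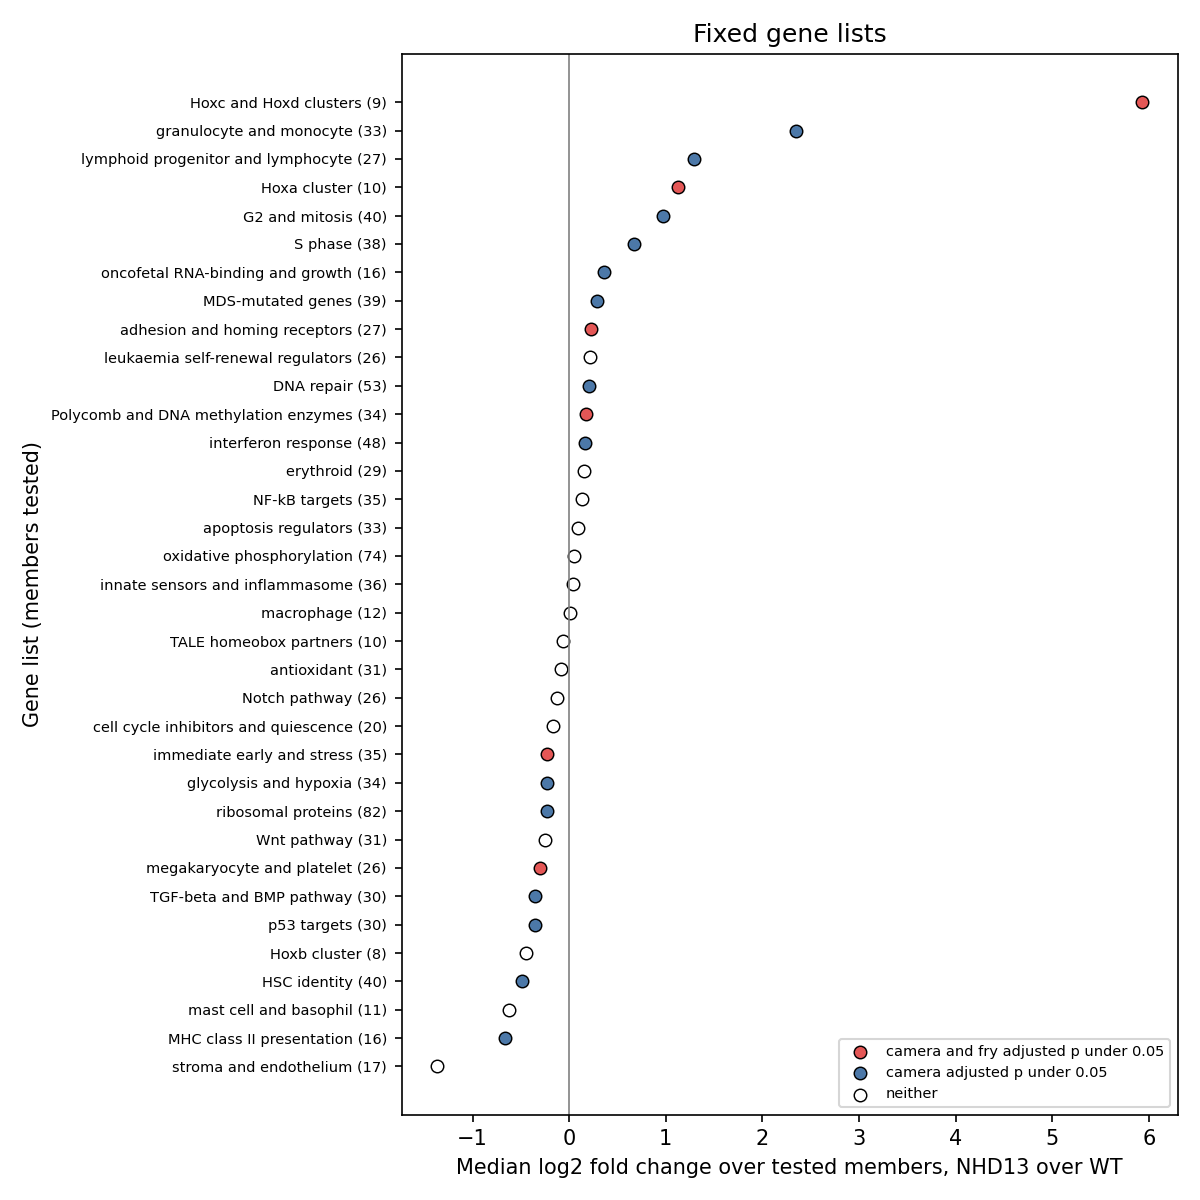
Median log2 fold change, NHD13 over WT, of the tested members of 35 gene lists fixed beforehand. Filled points passed an adjusted p of 0.05 by camera, and red ones also by fry; medians run from -1.37 for stroma and endothelium to 5.93 for the Hoxc and Hoxd clusters.

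Camera called 20 of the 35 lists, 12 higher and 8 lower, with its preset correlation. With an estimated correlation it called 0 and had 2 at an unadjusted p under 0.05, the smallest adjusted p being 0.464 and the smallest unadjusted p 0.0389. Fry, which asks whether a list's genes move one way, called 6. These were the Hoxc and Hoxd, Hoxa, megakaryocyte and platelet, adhesion, immediate early and Polycomb lists. Fry did not call the other lists that camera called. Its adjusted p was 0.118 for stem cell identity, 0.138 for G2 and mitosis and 0.207 for S phase. It was 0.234 for granulocyte and monocyte genes and 0.086 for MHC class II.

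Among named genes with the largest changes, several were close to absent in one group. Chga, which encodes a secretory granule protein of neuroendocrine cells, had 0 counts in WT and 574 in NHD13, at least 184-fold higher against a floor of 3 counts over the group. Gria2, a glutamate receptor subunit gene, had 3 counts in WT and a ratio of 551 (95% counting interval 188 to 2675). Meox2, a homeobox gene, had a ratio of 303 (83.5 to 2507), Khdrbs2 one of 301 (82.8 to 2487) and Itgb8 one of 172 (47.2 to 1425). The ephrin receptor gene Epha3 was at 81.5 ± 20.6 CPM against 0.154 ± 0.14, Mab21l2 at 285 ± 168 against 0.881 ± 0.303 and Cxcl15 at 20.6 ± 14.1 against 0.148 ± 0.177. Mab21l2 and Cxcl15 were not called without a filter (adjusted p 0.0554 and 0.112) or by limma-voom (0.0613 and 0.128), nor was Itgb8 by limma-voom (0.0559). Lrrn1 had 389 counts in WT and 0 in NHD13, at least 135-fold lower. Akr1c19 had a WT to NHD13 ratio of 574 (103 to 22710) and Isl1, a homeobox gene, one of 211 (58.0 to 1748). On the log2 scale Wfdc2 (-6.06 ± 0.23), B3galt1 (-5.78 ± 0.30), Clec1a (-5.35 ± 0.12) and Snhg18 (-6.14 ± 0.99) fell. Snrpn and Snurf, which overlap and held identical counts so that their reads cannot be told apart, fell by 5.31 ± 0.56. These intervals and floors cover counting error only.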

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

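Summing transcripts, testing every transcript, leaving out Rn45s and crossing the replicate numbers were chosen after seeing the data. None of the 636 called genes changed direction in any alternative tested by gene that called it again. As the alternatives reused the libraries that had selected these genes, this is weak evidence. DESeq2 called 2607 genes (1200 higher, 1407 lower), and a threshold of 0.1 gave 1923 (888 and 1035). With no filter 1138 were called (532 and 606), with a CPM of at least 1 in both libraries of a group 1066 (467 and 599), and with summed transcripts 402 (190 and 212). The cause of these differences was not tested. Leaving out 1 library in turn gave 0 to 990 genes, 0 to 449 higher and 0 to 541 lower, and 0 to 2 Hoxa genes, with the lone library of a group assumed to vary like the other group. Replicate numbers were shared between groups without a stated pairing, and the deviations of same-numbered libraries had a correlation of -0.206. A fit with the replicate number as a block called 107 genes (66 higher, 41 lower) and 0 Hoxa genes (5 at an unadjusted p under 0.05), with 1 residual degree of freedom; edgeR then had 3088 genes at an unadjusted p under 0.05. The crossed pairing as a block called 647 genes and 2 Hoxa genes. Camera called 0 lists with an estimated correlation and fry called 6.

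Changes of sign, of a value or of the direction of a list's test, occurred in results that the main test did not call. Some of these, such as Flt3 and the stroma and erythroid lists, were called in a fit without 1 library, as given above. The medians of TALE partners and cell cycle inhibitors stayed below 0 when a library was left out. The antioxidant list turned in the test without a filter (median -0.10), and the NF-kB list turned in the test under the stricter filter (median 0.10) and the block (median 0.017). The block also turned the macrophage median to -0.083 and the mast cell median to 0.30. Leaving out 1 library moved Flt3 between -1.57 and 2.20 and Slamf1 between -0.10 and 0.18 on the log2 scale. It moved list medians between -0.024 and 0.12 for NF-kB targets, -0.28 and -0.038 for TALE partners, -0.080 and 0.024 for antioxidant genes, -0.21 and -0.015 for cell cycle inhibitors, -1.02 and 0.58 for mast cells, -0.0075 and 0.12 for oxidative phosphorylation and -2.54 and 0.26 for stroma. For erythroid genes it gave -0.17 to 0.95, for macrophages -0.095 to 0.16, for apoptosis regulators -0.0011 to 0.068, for Notch -0.66 to 0.013 and for Wnt -0.45 to 0.060. Among called lists the granulocyte and monocyte median ran from 0.39 without NHD13 library 1 to 3.11 without NHD13 library 2, and the lymphoid median from 0.19 without NHD13 library 2, where the call was lost (adjusted p 0.0666), to 1.77 without WT library 1. The adhesion list missed the threshold without WT library 1, NHD13 library 1 or NHD13 library 2, with a median of 0.00060 without NHD13 library 1. Calls near the threshold were lost and gained. Without a filter Mab21l2 (adjusted p 0.0554), Cxcl15 (0.112), Mmrn1 (0.0847), Lin28b (0.103) and Ncf4 (0.0543) missed it, and with library totals only Hoxb5, Cd79a, Fcer1a, Rbl2, Plk2, Nfkb1, Jarid2 and Snhg18 did. Rbl2 and Plk2 also missed it in the non-robust fit (0.0506 for each). With limma-voom Mab21l2, Cxcl15, Ncf4, Itgb8 and Ezh2 did, and with summed transcripts these but Mab21l2 did, as did Hoxa5, Pbx4, Hlf, Psmb8 and the genes that missed it with library totals. The Hoxb list was called under the stricter filter (median -0.62, adjusted p 0.0138), and Meis1, Rplp1 and Rpl14 passed with library totals only, without a filter and under the stricter filter. Without NHD13 library 2 edgeR called 12 of 13 late granulocyte genes. Over the alternatives, 368 values of named genes kept their direction but missed the threshold and 1250 kept direction and side; for gene lists these were 50 and 302. At 2 libraries per group, changes under 4-fold were often missed in simulated data, where 37.6 percent of 2-fold changes were recovered.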

Other observations

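The tests on early granulocyte genes, on the level below which genes fell, on Cd48 and on the counts of imprinted genes were chosen only after the results were seen, as was the list of developmental regulators. Of 39 tested non-Hox homeobox genes and related developmental regulators 7 were called, 5 higher and 2 lower. The median was 1 in 10000 random lists matched on expression (permutation p 4e-04). Besides Meox2, Mab21l2 and Isl1, which had been seen before the list was written, as had Eya4 (4.84 ± 0.19) and Dach2 (3.06 ± 0.18), the called members included Lhx2, with 2 and 0 counts in WT and 59 and 264 in NHD13. As members seen beforehand make up most of the count, its p does not stand as independent evidence. Of the 39, 25 were at 1 CPM or more in WT. Members near absent in WT, such as Meox2 and Lhx2, passed the filter on low counts only through the NHD13 libraries, which matching on expression does not remove.

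Every library held both Xist, made by female cells, and Y-linked transcripts, as material of both sexes in each would give. Xist was at 104 and 276 CPM in WT and 665 and 392 in NHD13, and Ddx3y was at 169 and 128 in WT and 91.9 and 124 in NHD13. Xist had a log2 fold change of 1.48 ± 0.53, and the 4 Y-linked genes Eif2s3y (-0.66 ± 0.22), Ddx3y (-0.46 ± 0.20), Uty (-0.39 ± 0.17) and Kdm5d (-0.35 ± 0.33) all lay below 0. Xist was higher in both NHD13 libraries than in both WT ones and Eif2s3y, Ddx3y and Uty were lower, while Kdm5d overlapped between the groups. The values leaned the way a more female balance in NHD13 would give. This was not tested against RNA or reads crossing between samples. Without a block edgeR called none of these 5 genes (2 at an unadjusted p under 0.05; adjusted p 0.170 for Xist and 0.232 for Ddx3y), DESeq2 called 1 and limma-voom 0, and with the crossed pairing as a block edgeR called 2.

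Late granulocyte genes were high in NHD13 library 1 alone, with a median log2 ratio of 2.82 over NHD13 library 2 for all 13 tested members of the fixed list. A candidate explanation is mature neutrophils or their RNA in that library, although the lineage-negative gate would remove such cells. Among 25 other neutrophil genes the median log2 ratio of library 1 over library 2 was 1.41, above the bound of 1 set before it was computed. Of the 25, 12 were at 1 CPM or more in WT. The value was also 1.41 over the 27 genes first listed, before Hp and Cybb were left out as already seen in these data. For the 25 genes the median log2 ratio over WT was 2.06 in library 1 and 0.614 in library 2, and 6 were called higher. Their rise was larger in library 1. Members near absent in WT could pass the filter on low counts only if both NHD13 libraries held them. The library 2 value and the calls were thus in part given, and do not settle whether the rise was limited to library 1. Late granulocyte expression in neutrophils or in the sorted cells would pass this bound alike, so it does not tell these sources apart. Early granulocyte genes had a median log2 ratio over WT of 2.48 in NHD13 library 2, where the late genes had 0.204. Mature neutrophils in NHD13 library 1 could not raise the early genes there. As 4 of these 5 early genes had been called higher before the median was taken, it is not independent evidence. A rise of early granulocyte genes within the sorted cells, or other progenitors in the gate, stays open.

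Stem cell genes fell while Cd48 rose, and the gate did not use CD48. A mixture in which WT-like stem cells still gave most of the RNA could not lower any gene far. Yet 234 called genes lay below 50 percent of their WT level by more than 2 standard errors. Among them were 5 of the 7 called stem cell genes. Such falls had been seen before this bound was set, and the genes were picked as called, so the count describes these genes and is not an independent test. Near-complete replacement by CD48-positive progenitors that pass the same gate cannot be told apart from a change of the NHD13 stem cells themselves: the fitted log2 fold change of Cd48 was 5.63, with 267 and 223 CPM in the NHD13 libraries against a WT mean of 4.95, and bulk counts do not separate cells. The effect of the transgene within stem cells stays open and untested.

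Imprinted genes drew attention through Ndn, Snrpn, H19, Igf2 and Dlk1, and 10 of 55 tested members of a list of imprinted genes were called, 7 higher and 3 lower, against a median of 2 in matched random lists (permutation p 5e-04). That p is not independent evidence, since called members prompted the list. Low counts argue little here, since 10 called members had a mean count of at least 50, though Snrpn and Snurf share their reads and count as 1. The hypothesis that imprinted genes change more often than other genes was tested on the 39 members not seen beforehand: 2 were called, Igf2r and Xlr4c, against a median of 2 in matched random lists (permutation p 0.504). As first run, before Mest and Slc22a3 were also set aside as already seen, it gave 2 of 41 (permutation p 0.530). That test decides nothing, as judged after its result was known: 8 of the 16 members set aside as seen were themselves called (permutation p 0.504 for the rest), so the rest was stripped of calls. Whether imprinted genes change as a class stays open.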
